A study of Mus musculus with 3 samples.

How the data were processed

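Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 3 fractions of CD4+ T cells sorted from the lymph nodes that drain the mouse colon. Naive T cells carrying the transgenic CBir1 receptor, which recognises a flagellin of gut bacteria, were labelled with a dye that is diluted at each division and were transferred into 4 wild-type recipients. The recipients drank 2% dextran sulfate sodium (DSS), which damages the colon epithelium, for 7 days. They received the drug FTY720, which keeps lymphocytes in lymph nodes, at 1 mg/kg on days 7, 10 and 13, and their nodes were taken on day 14 after DSS began. The fractions were CBir1 cells that had diluted the dye (divided), CBir1 cells that had kept it (undivided) and the recipients' own CD4+ cells (polyclonal). Per the labels, each pool combined 2 mice and pools were made in duplicate, but 1 peak list per fraction was analysed here, and how the duplicates entered it is not given in the sources used here. Each group is therefore 1 library, no difference has a replicate check, and no p-value between groups was computed.

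The submitters' processing notes name bcl2fastq 2.17, cutadapt 1.12, Trimmomatic 0.33, Bowtie2 2.3.2, Picard, SAMtools, MACS2 2.1.0 and the mouse build mm10. Whether reads were shifted for the transposase offset, which would move summits by a few bases, is not given in the sources used here. The deposited peak lists give each peak's start, end and summit offset, a score that is the −log10 q-value multiplied and cut to a whole number, the fold enrichment over local background as a linear ratio, and the −log10 p-value and −log10 q-value. The deposited summit lists repeat the summit positions and −log10 q-values. The lowest deposited −log10 q-value was 1.31 in the divided, 1.30 in the undivided and 1.30 in the polyclonal list, which is a q threshold of about 0.05, and the narrowest peak was 150 bp in each list. Rows of 1 peak with several summits were counted once. The authors' fold and −log10 q belong to each peak within its own list. They were used to describe, rank and filter peaks.

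Read totals are not given in the sources used here. The number of fragments piled up at each summit and the local background were recovered from the deposited fold, taken as (pileup + 1)/(background + 1), and the deposited −log10 p-value under a Poisson model. A whole-number pileup within a tolerance of 0.001 was found for 99.94% of divided, 99.96% of undivided and 99.97% of polyclonal peaks. The lowest background, 1.21, 0.808 and 0.865 fragments in the divided, undivided and polyclonal library, is proportional to depth if all libraries were piled up with the same settings. By this proxy the divided library was 1.50 times as deep as the undivided and 1.40 times as deep as the polyclonal library. In regions called in all 3 libraries the median pileup ratio was smaller, at 1.21 and 1.19. Pileup over background is the summit pileup divided by the library's lowest background.

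Peaks of the 3 lists that overlapped by at least 1 bp were merged into regions, and a region was called in a library if a peak of that library lay in it. Shares have Wilson 95% intervals, which cover counting error only. Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. The table gives gene spans without strand or exons. The design had named the nearest transcription start site. In its place each region was assigned to the nearest protein-coding gene span within 100 kb (distance 0 inside a gene), which left 3032 regions without a gene. A region near a gene end overlapped the 1 kb either side of a gene's first or last base, and exons and introns were not told apart. The planned motif search was not run, since no genome sequence was used here.

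For genes and gene lists, a region counted for library A against library B when its peak in A had a −log10 q of at least 5 and B had no peak there at the authors' threshold. A gene's net count is its A-only regions minus its B-only regions. Lists written before the data were examined held 12 sets of T cell genes (Th1, Th17, Th2, Treg, Tfh, naive and quiescence, activation and effector regulators, inhibitory receptors and anergy, migration and gut homing, cytotoxic effector, cell cycle, T cell identity) and 8 sets of markers (B cell, myeloid, dendritic cell, CD8 T cell, NK and innate lymphoid, epithelial, stromal and endothelial, erythroid). The mean net count of a list was ranked among 10000 random lists of equal size matched on the number of regions per gene in 20 bins. A list stands apart below percentile 2.5 or above 97.5. This describes these libraries, and 5% of the 60 tests (12 T cell and 8 marker lists in 3 comparisons) would lie outside by chance. Genes were named by a rule set in advance: in each comparison the 2 members of each T cell list with the largest absolute net count, the 4 genes of the genome with the highest and the 4 with the lowest, and, for divided against undivided, always Ifng, Tbx21, Il17a, Foxp3, Bcl6, Gata3, Ccr7 and Tcf7, with some further genes that are not reported here. The region given for a gene is its one-sided region of highest −log10 q. Members named for markers, leave-one-out values and the closing section were chosen after their values were seen, as stated there.

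Alternatives set in advance were stricter −log10 q thresholds of 5 and 10, equal peak numbers, reciprocal overlap of 50%, windows of 250 bp either side of summits, a common minimum of 10 times background, autosomes only, assignment within 20 kb or by gene span with 10 kb flanks, and removal of regions near gene ends. Depth-limited counts, a common minimum scaled by shared regions, and lists without 1 member were added after seeing the data. Depth-limited counts start from all one-sided regions at the authors' threshold, without the −log10 q of at least 5. Of these they keep only regions that the other library would have called with a probability of at least 0.95 at the same pileup after scaling. A depth-limited count can therefore exceed the main count. Pileups were scaled by the ratio in shared regions unless stated, and by the background ratio as a further alternative (by background). Code was tested on simulated data. All 5000 simulated peaks gave back their pileup, all 3000 simulated regions their class, and 4.50% of 400 unchanged lists stood apart. Among 40000 unchanged regions in 2 simulated libraries with a depth ratio of 1.50, the deeper library held 72.2% of one-sided regions at a fixed threshold and 47.8% with the common minimum. Depth-limiting left 303 regions in the deeper and 309 in the shallower library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.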

Results

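Accessible chromatin was compared between divided and undivided CBir1 T cells and the polyclonal CD4+ T cells of the same lymph nodes after DSS colitis. The aim was to describe how these fractions differed within the colitis setting. Every fraction came from recipients given DSS and FTY720, with no untreated library, so an effect of inflammation itself cannot be read from them. The divided list held 47963 peaks, the undivided 41876 and the polyclonal 44426, covering 29.8, 25.3 and 26.4 Mb. Median peak widths were 522, 519 and 503 bp, and median summit pileups were 31, 30 and 27 fragments. There was 1 library per fraction, so every difference below is between libraries and has no replicate check. The divided library was also the deepest by its background, 1.496 times the undivided one.

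Merging the lists gave 57457 regions, of which 32680 (56.9%, 95% interval 56.5 to 57.3) were open in all 3 fractions. Divided cells alone held 8223 regions (14.3%), undivided cells alone 3621 (6.30%) and polyclonal cells alone 4302 (7.49%). Divided and polyclonal cells shared 4061 regions that were not called in undivided cells, against 2278 shared by the 2 CBir1 fractions only and 2292 shared by undivided and polyclonal cells only. Regions common to all 3 lay near a gene end in 33.3% of cases (32.8 to 33.8), and the 16146 regions called in 1 library in 8.80% (8.37 to 9.25). The common regions were also wider, and wider regions meet this overlap rule more easily. Their median width was 782 bp, against 251, 224 and 224 bp for regions of divided, undivided and polyclonal cells alone. In every library all 14 T cell identity genes (among them Cd3e, Cd4 and Lck) and all 14 cell cycle genes had a peak at a gene end.

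**Figure D1:**
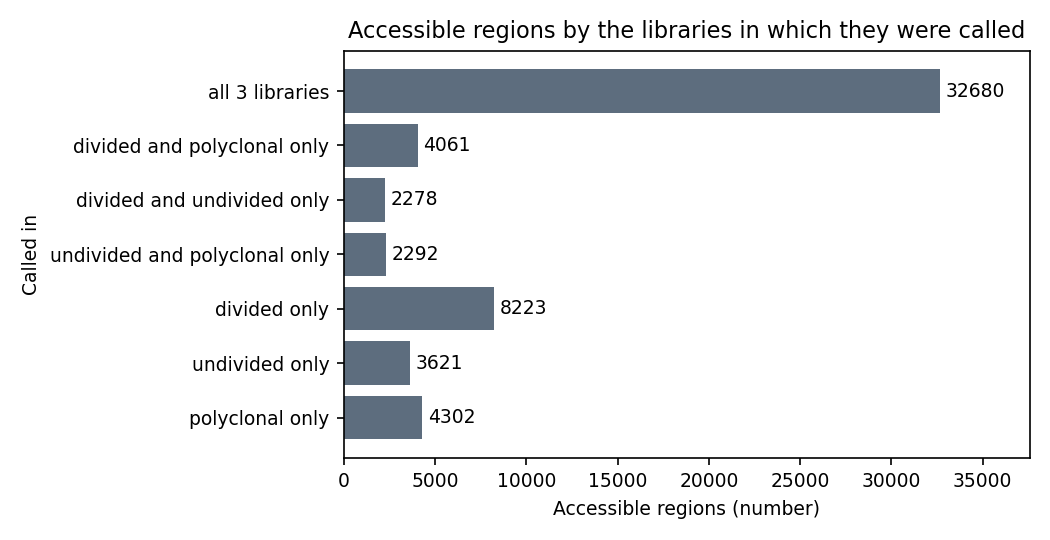
Number of accessible regions (horizontal axis) by the libraries in which they were called (vertical axis), 1 library per fraction. Most regions, 32680, were called in all 3 libraries, and the divided library held the most regions called in 1 library alone, 8223.

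The comparison of divided with undivided CBir1 cells asks how the chromatin of cells that had proliferated differed from that of cells that had not. Under the rule used for genes, all regions together gave 7145 against 2837, a divided share of 71.6%. Counts at single genes are to be read beside that share. Genes of follicular helper T cells and of Th17 cells carried more regions open in divided cells than matched genes did. The Tfh list had 23 regions called in divided and not undivided cells and 2 of the opposite kind (percentile 99.4), with 6 of its 11 members net toward divided and 0 toward undivided. Icos, which encodes a costimulatory receptor, had 9 against 1, Il21, a helper cytokine gene, 6 against 1, and Maf, a transcription factor gene chosen after its values were seen, 4 against 0. The Th17 list had 20 against 1 (percentile 99.4), led by Rora, which encodes a nuclear receptor of Th17 cells, with 10 against 0 and the aryl hydrocarbon receptor gene Ahr with 4 against 0 (2 against 0 depth-limited). B cell markers stood apart in the same direction (5 against 0, percentile 97.6). Both T cell calls rested partly on single genes: the Tfh percentile was 95.2 without Icos (97.8 depth-limited) and the Th17 percentile 87.2 without Rora (77.0 depth-limited). The Tfh percentile was also 89.2 with assignment within 20 kb and 93.0 by gene span, and the Th17 percentile was 95 at a −log10 q of at least 10.

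The other T cell lists did not stand apart, although most had more regions on the divided side. Th1 genes had 20 against 5 (percentile 89.0), of which Ifng, the Th1 cytokine gene, gave 9 against 0 and the transcription factor gene Stat4 3 against 0. Without Ifng the Th1 percentile was 41.9. Treg genes had 21 against 7 (85.2), with Il10, an anti-inflammatory cytokine gene, at 5 against 0 and Nrp1 at 7 against 2. Inhibitory receptor and anergy genes had 21 against 6 (88.1), with 3 against 0 at Lag3 and 4 against 1 at Nt5e, and 10 of 14 members were net toward divided. Cytotoxic genes had 8 against 0 (95.7, and 97.8 at a −log10 q of at least 10 or 97.9 and 97.6 depth-limited by shared regions and by background), including Fasl with 3 and Gzmk with 2. Activation regulators had 20 against 6 (69.8), with 3 against 0 at both Cd44 and Prdm1. Th2 genes had 6 against 0 (85.2, and 97.56 depth-limited by background), with 2 at Il1rl1 and 1 at Rad50, which spans the control region of the Th2 cytokine genes. Migration genes had 10 against 3 (60.7), with 3 against 0 at the integrin gene Itga4 and 0 against 2 at the chemokine receptor gene Cxcr4. T cell identity genes had 21 against 8 (72.1), with 6 against 2 at Cd28 and 4 against 1 at Cd247. Naive and quiescence genes had 31 against 22 (25.4), with 4 against 0 at Ccr7 (a net of −1 depth-limited by background) and 4 against 1 at S1pr1 (a net of −1 by gene span), and cell cycle genes had 0 against 0 (15.8).

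The lineage genes named here had few regions called on 1 side only. Tbx21, Bcl6 and Il17a had 0 regions on either side, and Foxp3, Gata3 and Tcf7 had 1 in divided cells only (depth-limited 0, 2 and 2). A count of 0 does not mean equal signal. At a region 9587 bp from Il17a, chosen after its values were seen, the pileup was 110 in divided and 6 in undivided cells. It was called in both and so did not count. The Foxp3 region (chrX:7587485-7587841, inside the gene) was weak, with a pileup of 14 fragments and a −log10 q of 5.71. By contrast the Cd44 region lay 55422 bp from the gene (chr2:102956748-102957433) and had a pileup of 88 and a −log10 q of 75.9 in divided cells. The Il10 region, 9222 bp from the gene (chr1:131010302-131010944), had a pileup of 55 and a −log10 q of 34.3. At Lag3 a region near the gene end (chr6:124911372-124912219) reached a pileup of 80 and a −log10 q of 42.4. The Rad50 region (chr11:53656725-53657188, inside the gene) reached 36.8. These 5 regions were also called in polyclonal cells. The strongest Ifng region, 13072 bp from the gene (chr10:118458759-118459173, pileup 36, −log10 q 15.01), was called in divided cells only. Of the regions named for the undivided side, the one with the highest −log10 q belonged to Cxcr4 (chr1:128602291-128603204, 10449 bp away, pileup 84, −log10 q 43.6), and it too was called in polyclonal cells.

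**Figure D2:**
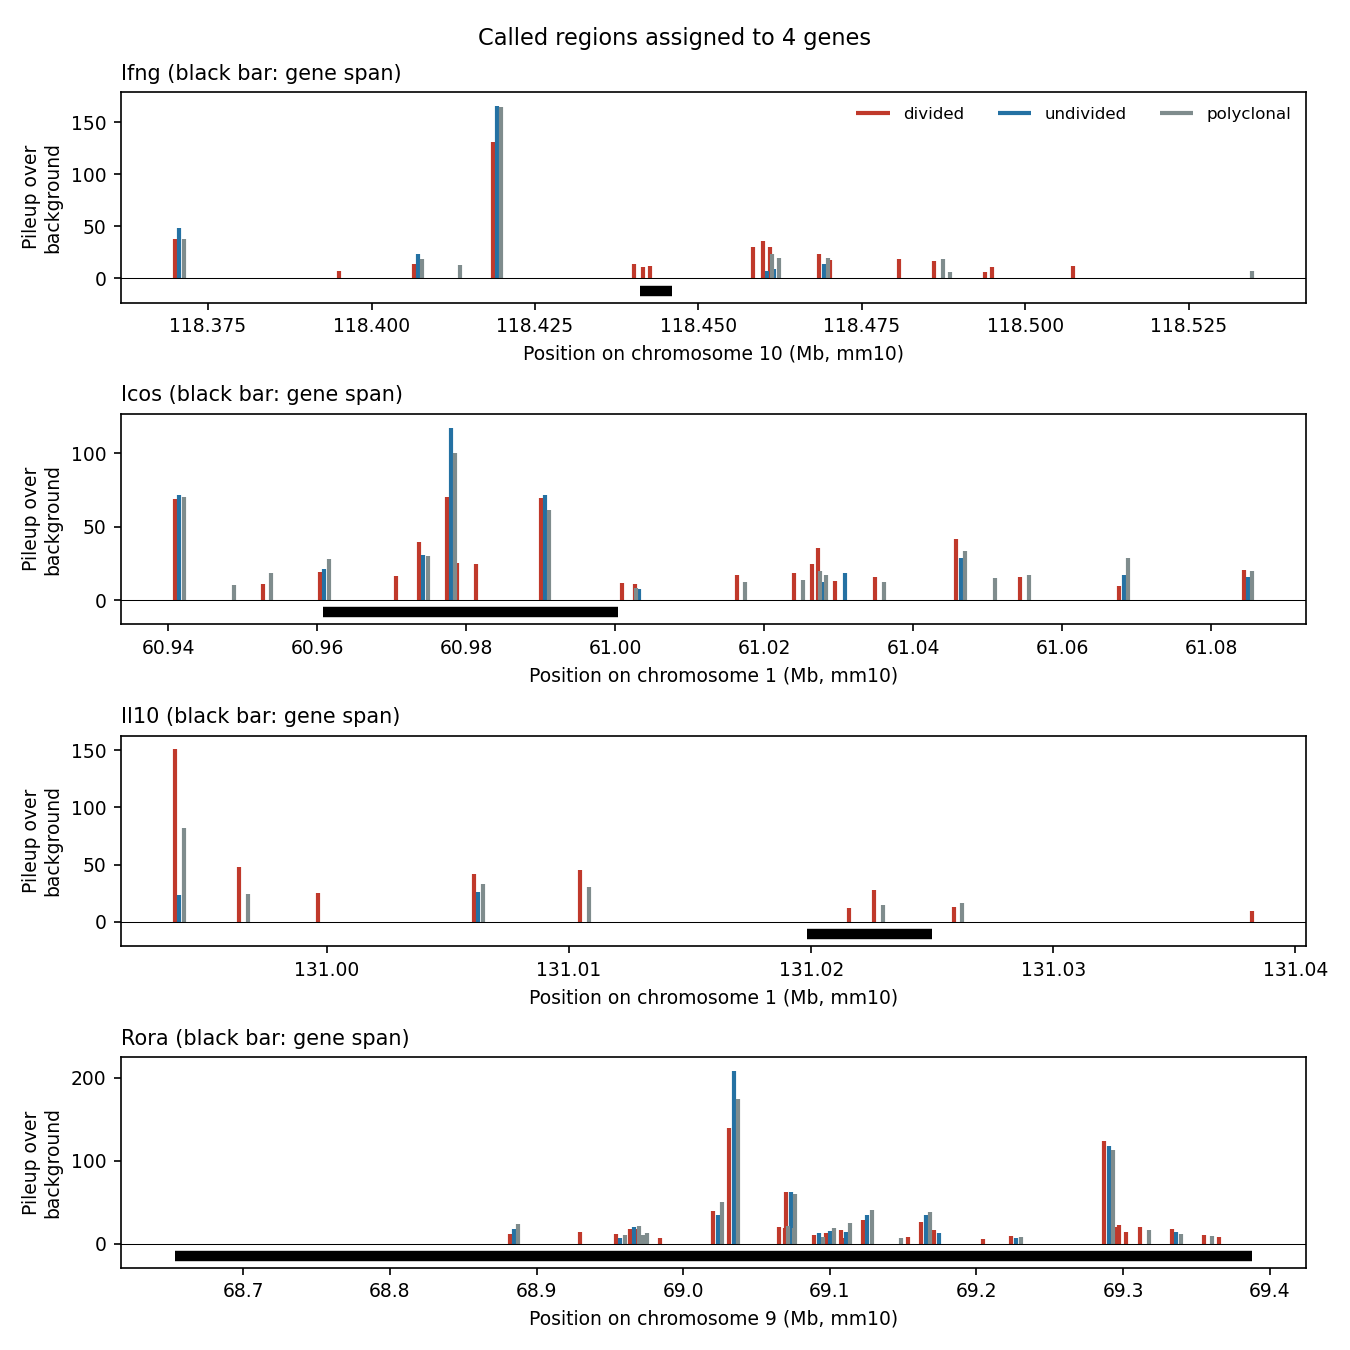
Pileup at the summit over the library's lowest background (vertical axes) for called regions assigned to Ifng, Icos, Il10 and Rora, by position in Mb (horizontal axes), with 1 bar per library, shifted sideways for clarity, and the gene span in black; a missing bar means no peak in that list. Around Ifng 9 regions passed the −log10 q of 5 in divided cells without a peak in undivided cells, and around Il10 5 did.

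Across the genome, the genes with the highest net counts toward divided cells were Rad51b (14 against 0), Wwox (16 against 4), Trerf1 (12 against 0) and Etv6 (10 against 0, as many as Rora). Net counts were not scaled by the regions assigned to a gene, which numbered 33 at Rad51b, 63 at Wwox, 20 at Trerf1 and 27 at Etv6. The strongest Wwox region (chr8:115136644-115137273, inside the gene) had a pileup of 65 and a −log10 q of 53.5. Toward undivided cells the genes with the most extreme net counts were Hecw2 (1 against 7), Plcl2 (0 against 5), Tspan9 (0 against 5) and Dad1 (1 against 6). The Dad1 region of highest −log10 q on the undivided side (chr14:54147172-54147958) lies inside the T cell receptor alpha and delta locus, and depth-limited Dad1 had 4 against 5. Of all regions, 12284 were called in divided and not undivided cells and 5913 in undivided and not divided cells, so that divided cells held 67.5% (66.8 to 68.2) of one-sided regions. That share depended on how depth was treated: with pileups scaled by shared regions it was 68.0% depth-limited and 70.3% with a common minimum, and with pileups scaled by background 48.3% and 56.5%.

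Markers of other cells showed small counts. B cell markers stood apart toward divided cells with 5 regions against 0 (percentile 97.6, but 89.4 and 96.8 depth-limited by shared regions and by background, 95.7 at the authors' threshold and 84.4 without regions near gene ends). The regions, named after their values were seen, were at Pax5 (2), Blk (2) and Ebf1 (1). The stronger Pax5 region (chr4:44624478-44625310, inside the gene) had a pileup of 63 in divided and 20 in polyclonal cells. Of the markers, 5 of 10 had a gene-end peak in divided, 2 in undivided and 3 in polyclonal cells. Ms4a1, the gene of a B cell surface protein, had no gene-end peak in any library. CD8 T cell markers had 1 against 3 (4.23, but 0.44 within 20 kb and 2.05 depth-limited by background), and myeloid (5 against 2, percentile 48.8), dendritic cell (3 against 2, 39.9), NK and innate lymphoid (2 against 0, 63.9), epithelial (3 against 2, 47.8), stromal and endothelial (6 against 2, 72.7) and erythroid markers (0 against 1, 4.27) did not stand apart.

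**Figure D3:**
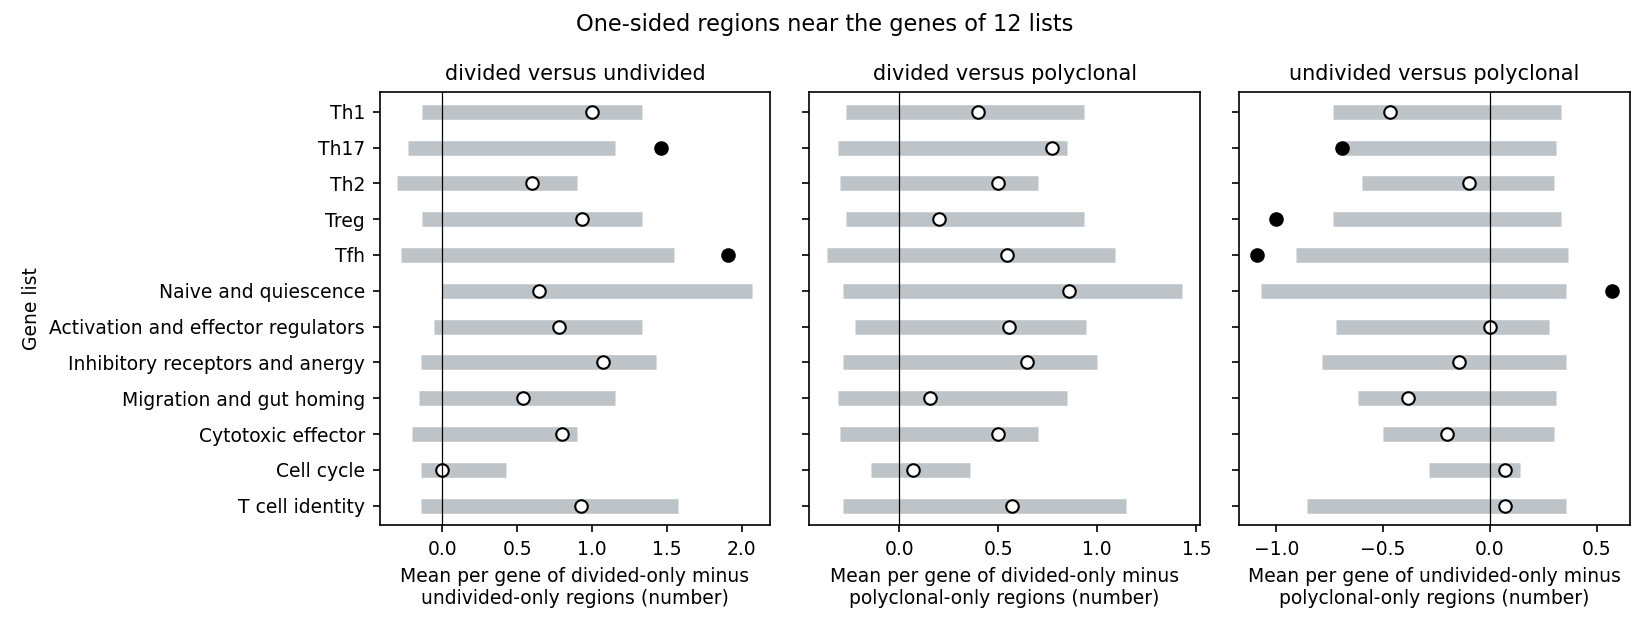
Mean net count of one-sided regions per gene (horizontal axes, number) for 12 T cell gene lists (vertical axis) in the 3 comparisons, 1 library per fraction. Grey bars span the middle 95% of 10000 matched random lists and filled points lie outside it, as Th17 and Tfh do for divided against undivided at percentile 99.4.

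Divided CBir1 cells were then set against polyclonal CD4+ cells, the mixed endogenous population of the same nodes. No T cell list stood apart. Th17 genes came nearest with 13 regions against 3 (percentile 95.5, with 99.8 at the authors' threshold but 65.0 without Rora), with 6 against 0 at Rora and 0 against 2 at the chemokine receptor gene Ccr6. Around Ifng, divided cells had 8 regions against 1, which placed it among the 4 highest genes of the genome, while Eomes, a T-box factor gene of the same list, had 0 against 4. Th1 genes together had 15 against 9 (61.0).

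The remaining lists were Th2 with 5 against 0 (88.1), cytotoxic with 5 against 0 (90.3), inhibitory receptors with 12 against 3 (81.9), activation regulators with 15 against 5 (75.9), naive genes with 30 against 18 (75.1, and 99.3 at a −log10 q of at least 10), Tfh with 7 against 1 (71.2), T cell identity with 14 against 6 (69.8), cell cycle with 1 against 0 (43.3), Treg with 12 against 9 (34.6) and migration with 5 against 3 (33.6). Members with most regions on the divided side were Nrp1 (5 against 0), Icos, Cd247 (both 3 against 0), Bach2 (8 against 5), Myc (3 against 1), and Maf, Batf, Il1rl1, Nt5e, Itga1 and Fasl (each 2 against 0, but Itga1 0 against 0 depth-limited). Scaled by background, depth-limited Icos and Bach2 turned to a net of −1 and −3. Ccr4, Egr2, Klrg1 and the cell cycle gene Rrm2 had 1 against 0. A region 64248 bp from Maf (chr8:115770932-115771352) was called in divided cells alone with a pileup of 58 and a −log10 q of 60.5. On the polyclonal side were Lef1, a factor of naive cells (2 against 6, but a net of 1 at a −log10 q of at least 10), Cd3e (0 against 3), Cxcr4 and Lrrc32 (both 0 against 2).

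Trerf1 (9 against 0), Rad51b (8 against 0) and Atxn1 (7 against 0) were, with Ifng, the highest genes of the genome in this comparison, and Tspan9 (0 against 6), Egfr, Tbc1d22a and Trpm1 (each 0 against 5) the lowest. In total 10501 regions were called in divided and not polyclonal cells and 6594 in the opposite direction, a divided share of 61.4% (60.7 to 62.2) that turned to 49.3% with a common minimum over background and to 42.7% depth-limited by background. Under the rule used for genes the totals were 5586 and 2866. Of the marker lists, B cell (2 against 1, percentile 53.2), myeloid (8 against 2, 91.1), dendritic cell (2 against 1, 51.0), NK and innate lymphoid (3 against 0, 89.3), epithelial (1 against 1, 31.1), stromal and endothelial (3 against 1, 61.0) and erythroid markers (0 against 0, 41.4) did not stand apart. CD8 T cell markers had 1 against 3 (6.51, and 0.18 at the authors' threshold).

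In undivided CBir1 cells, genes of 3 helper and regulatory lists had fewer one-sided regions than in polyclonal cells, and naive genes more. Treg genes had 5 regions called in undivided cells and 20 in polyclonal cells (percentile 0.30), with 9 of 15 members net toward polyclonal. Il10 had 0 against 4 and Ctla4, which encodes an inhibitory receptor, 1 against 5. Tfh genes had 2 against 14 (0.73), with Icos at 1 against 5 and Maf at 0 against 3. Ctla4 (chr1:60909025-60915832) and Icos (chr1:60960773-61000322) lie close together, and regions were split between them only by the nearest gene span. The Treg and Tfh calls are therefore not fully separate. Th17 genes had 4 against 13 (2.095), with Rora at 1 against 4 and Ccr6 at 0 against 3 (0 against 1 depth-limited). Naive and quiescence genes went the other way with 24 against 16 (99.3), with Foxp1 at 4 against 1 (2 against 1 depth-limited), although Lef1 had 3 against 7. Foxp1 turned to a net of −4 at the authors' threshold. B cell markers moved the same way as the helper lists (0 against 5, percentile 0.19). The undivided library enters this comparison and the first, so their results are not independent. Each of the 4 calls was lost under at least 1 other setting, among them: Treg had a percentile of 23.4 at a −log10 q of at least 10 and 3.66 by gene span, Tfh 23.3 within 20 kb and 4.03 without Icos (1.62 depth-limited), Th17 14.6 and 12.97 depth-limited by shared regions and by background and 9.79 without Ccr6, and the naive list 93.2 at the authors' threshold and 97.2 without Foxo1.

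Other lists lay within the range of random lists: Th1 (3 against 10, percentile 14.7; Ifng and Eomes each 0 against 2), migration (0 against 5, 17.2; Gpr15, a gut homing receptor gene, and Gcnt1 each 0 against 2, with 0 against 1 at Gcnt1 depth-limited), cytotoxic (1 against 3, 27.3; Gzmk 0 against 2), Th2 (1 against 2, 46.5), inhibitory receptors (4 against 6, 58.6), activation regulators (4 against 4, 79.6), cell cycle (1 against 0, 83.0) and T cell identity (7 against 6, 84.95). The Gpr15 region (chr16:58718593-58719212) lay 31 bp from the gene and had a pileup of 34 and a −log10 q of 29.5 in polyclonal cells. The Il10, Cd44, Lag3 and Rad50 regions described for divided cells were absent from the undivided list and present in the polyclonal one, with −log10 q values of 18.5, 26.5, 14.3 and 10.98. Myc had 2 against 0 (1 against 0 depth-limited), and Ccr4, Nr4a3, Rrm2 and Cd4 had 1 against 0, while Cd3e had 0 against 2.

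Across the genome the highest genes toward undivided cells were Dad1 (7 against 1, but 5 against 2 depth-limited and a net of −1 by gene span), Zfp618, Mid1 and Fcgr3 (each 4 against 0), and the lowest were Wwox (1 against 13), Nsmce2 (0 against 6), Thada (2 against 7) and Palld (0 against 5). The undivided-side Dad1 region of highest −log10 q (chr14:54179031-54179225) lay 56357 bp from the gene, inside the T cell receptor alpha and delta locus. The Palld region (chr8:61606602-61607356, inside the gene) had a pileup of 47 and a −log10 q of 43.1. Undivided cells held 5899 and polyclonal cells 8363 one-sided regions, an undivided share of 41.4% (40.6 to 42.2). Under the rule used for genes the totals were 2611 and 3874. B cell markers stood apart toward polyclonal cells (0 against 5, percentile 0.19; 12.6 at a −log10 q of at least 10), at Ebf1 (3) and Pax5 (2). The CD8 T cell (0 against 0, 61.6), myeloid (5 against 3, 89.5), dendritic cell (2 against 1, 83.5), NK and innate lymphoid (0 against 1, 31.2), epithelial (1 against 0, 85.1), stromal and endothelial (1 against 3, 27.1) and erythroid markers (1 against 0, 94.5) did not stand apart.

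The T cell receptor loci were examined because CBir1 cells carry a rearranged transgenic receptor. In the beta locus (chr6:40891296-41558371) 44 regions were called, 17 of them in all 3 libraries, 6 in both CBir1 libraries only and 10 in polyclonal cells only. Over the 17, the ratio to polyclonal cells had a median of 1.31 in divided and 1.69 in undivided cells. It was below 2 at 13 and 10 regions and below 1 at 6 and 3 regions, so most were above the polyclonal value. The region at Trbv12-1 stood at 108 times background in divided, 115 in undivided and 117 in polyclonal cells, and the one at Trbv2 at 10.8, 13.6 and 24.3. In each CBir1 library 3 of the 17 were over 4 times the polyclonal value, at Trbv12-2, Trbj2-7 and behind Trbc2. The region overlapping Trbv12-2 (chr6:41118060-41119023) stood at 1261 times background in divided, 1989 in undivided and 102 in polyclonal cells. The neighbouring region at Trbv13-1 (chr6:41115951-41116754) stood at 473 and 822 times background in divided and undivided cells and was not called in polyclonal cells. The region between Trbc2 and Trbv31 (chr6:41553117-41555204) stood at 1077, 1962 and 258. For scale, regions near gene ends that were called in all 3 libraries had medians of 76.1, 90.4 and 89.0 times background. The alpha and delta locus (chr14:52427967-54224198) held 181 regions, of which 77 were called in all 3 libraries, 28 in undivided cells only, 21 in undivided and polyclonal cells only, 20 in divided cells only and 17 in polyclonal cells only. In the gamma locus (chr13:19178042-19352343) 6 regions were called. Chromosome X held 1475 regions, 776 of them in all 3 libraries, and chromosome Y 36, with none at Ddx3y, Uty, Eif2s3y or Kdm5d.

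**Figure D4:**
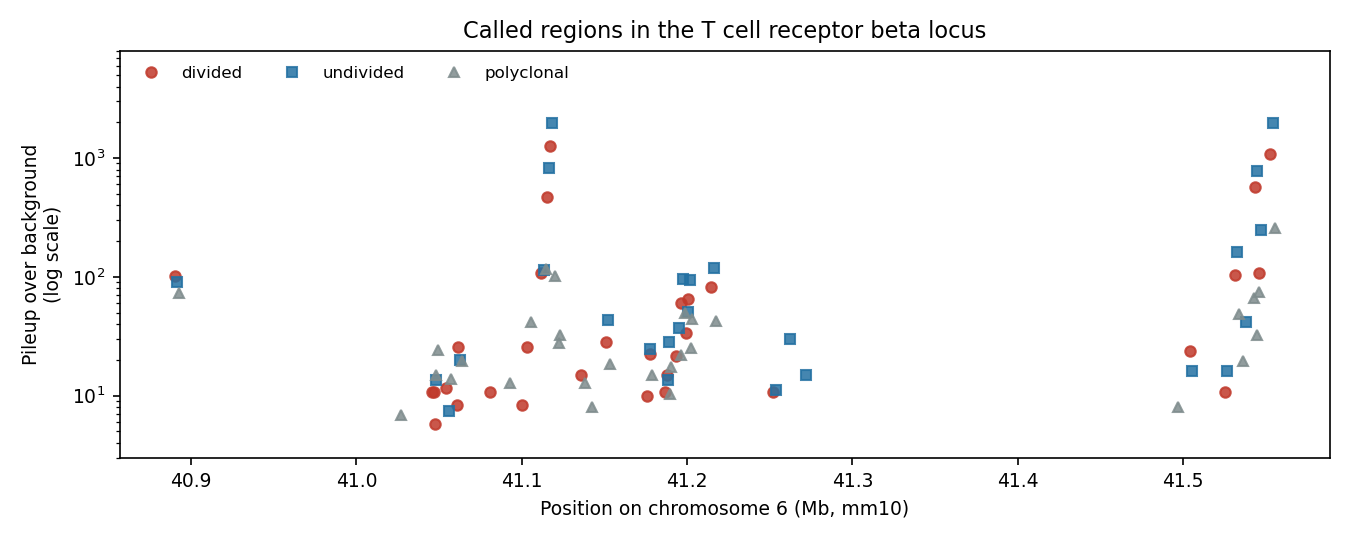
Pileup over the library's lowest background (vertical axis, log scale) of called regions in the T cell receptor beta locus by position on chromosome 6 in Mb (horizontal axis), with points of the 3 libraries shifted sideways for clarity. The highest points, at Trbv12-2, are at 1261 in divided and 1989 in undivided cells and at 102 in polyclonal cells.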

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

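No paired analysis was possible because each fraction has 1 library and no result comes from a test between samples. Motif alternatives were not run, since the motif search was not. The depth-limited counts by both scalings, the minimum scaled by shared regions and the lists without 1 member were chosen after seeing the data. Depth-limited counts are scaled by shared regions or, where stated, by background. Equal peak numbers force the share near 50% by construction, and the shares differ by the scaling chosen for depth. For other settings the cause was not tested.

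The divided share of regions called in 1 of divided and undivided cells, 67.5%, was 69.0% at −log10 q of at least 5 in both lists, 71.6% and 75.2% at 5 and 10 on the calling side, 51.7% with equal peak numbers, 60.8% with reciprocal overlap, 65.7% with summit windows, 56.5% or 70.3% with a common minimum over background or scaled by shared regions, and 68.0% or 48.3% (reversed) depth-limited by shared regions or by background. Against polyclonal cells the divided share, 61.4%, was in the same order 65.5%, 66.1%, 68.5%, 51.6%, 56.4%, 59.9%, 49.3% (reversed) and 65.3%, and 62.3% or 42.7% (reversed) depth-limited. The undivided share against polyclonal cells, 41.4%, was 43.2% and 40.3% at −log10 q of at least 5 in both lists and on the calling side, 49.6% with equal numbers, 44.6% with reciprocal overlap and 38.4% or 46.8% depth-limited.

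The percent of regions called in both libraries of a pair was, for divided and undivided cells (65.8%), 70.9%, 77.8%, 90.4%, 68.7%, 52.3%, 64.7%, 71.2% and 69.4% in that order of 8 settings, and 80.3% or 82.3% depth-limited. For divided and polyclonal cells (68.2%) it was 73.5%, 81.3%, 93.6%, 72.5%, 53.9%, 67.2%, 73.6%, 72.2%, 83.0% and 84.3%. For undivided and polyclonal cells (71.0%) it was 77.2%, 84.4%, 95.3%, 72.7%, 57.2%, 69.9%, 75.9%, 75.9%, 86.7% and 86.1%. With thresholds on the calling side only and with depth-limiting, only the one-sided regions were filtered. The count of regions called in both stayed that of the deposited lists. In these settings the percent rises by construction and does not measure agreement between libraries. Peaks at −log10 q of at least 10 numbered 31348 in divided and 28529 in polyclonal cells. The share near a gene end was 30.6% and 37.5% of regions called in all 3 libraries, and 5.32% and 14.6% of regions called in 1 library, within 500 bp and 2 kb.

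Of T cell lists, 2 stood apart for divided against undivided cells, 1 did within 20 kb and by gene span, and 4 did depth-limited by background. For divided against polyclonal cells 0 did, and 1 did at the authors' threshold and at −log10 q of at least 10. For undivided against polyclonal cells 4 did, and 2 did at the authors' threshold, at 10, within 20 kb and by gene span. Of marker lists, 1 stood apart for divided against undivided cells, 0 at −log10 q of at least 10 and without gene ends, and 2 within 20 kb. For divided against polyclonal cells 0 did, and 1 did at the authors' threshold, within 20 kb, by gene span and depth-limited by both scalings. For undivided against polyclonal cells 1 did, and 0 did at 10 and without gene ends. Reversed genes were S1pr1 (divided minus undivided −1 by gene span), Ccr7 (divided minus undivided −1 depth-limited by background), Lef1 (divided minus polyclonal 1 at 10), Icos and Bach2 (divided minus polyclonal −1 and −3 depth-limited by background), Dad1 (undivided minus polyclonal −1 by gene span) and Foxp1 (undivided minus polyclonal −4 at the authors' threshold). Of 784 values for single genes, 581 stayed within 1.5 times, 196 moved and 7 reversed. Of 480 for single lists, 443 kept their side of the threshold, 21 lost and 16 gained a place outside it. Of 66 counts of regions, 32 stayed within 1.5 times.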

Other observations

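The tests in this part were chosen after the results were seen, except that of gene assignment for the Tfh list. For the Tfh list without 1 member, the expected outcomes are recorded as written beforehand, although such lists were added after seeing the data. Beyond presence or absence, regions called in both libraries of a pair were compared by their recovered pileup, scaled so that regions called in all 3 libraries had a median ratio of 1. These ratios come from separately called lists of 1 library each, and lists were ranked among 10000 random lists matched on pileup. Genes in this part were named after their values were seen. Between divided and undivided cells, Tfh genes had a mean log2 ratio of 0.57 (above all 10000 random lists, with 10 of 11 members higher in divided cells; 0.35 without Angptl2, percentile 98.9) and Th17 genes 0.77 (percentile 99.99, with 6 of 9 members higher; 0.55 without Il17a, percentile 99.1). Ahr had a mean of 1.43. The largest ratio among regions with at least 50 fragments in the pair lay 9587 bp from Il17a (chr1:20743867-20744299), with 110 fragments in divided, 6 in undivided and 64 in polyclonal cells, a log2 ratio of 3.93 for divided over undivided. This region does not enter the one-sided counts, since a weak peak was called in undivided cells. Cell cycle genes, which had 0 one-sided regions, had a mean of 0.29 (percentile 99.7, 11 of 14 higher), with Plk1 at 0.87 (1 region) and Cdk1 at 0.76 (2 regions). Treg genes had 0.34 (99.3, 11 of 15 higher; 92.4 without Il10, whose mean was 2.00) and inhibitory receptor genes 0.27 (97.8, 11 of 14 higher; 93.7 without Rnf128). Naive and quiescence genes had −0.20 (percentile 0.30, 11 of 14 lower in divided cells), with Dapl1 at −0.50 and Satb1 at −0.42. Cytotoxic genes had −0.38 (0.13, 6 of 8 lower, and 2.56 without Klrd1), opposite in sign to the one-sided counts of the list. Prf1 was at −1.05 (2 regions) and Klrk1 at −0.93 (1 region). Each gene counted equally in the mean, and Fasl, with 14 regions, was at −0.07. NK and innate lymphoid markers had −0.37 (1.93, 3 of 4 lower), and the other marker lists measured lay at percentiles 6.94 to 75.7.

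Against polyclonal cells, divided cells had higher means for Th1 (0.36, percentile 99.6, 8 of 13 members higher; 90.7 without Ccl5), Tfh (0.33, 99.3, 10 of 11) and inhibitory receptor genes (0.24, 98.6, 10 of 14; 92.1 without Havcr2, which encodes an exhaustion-associated receptor and had 1.35), while all marker lists measured lay at percentiles 5.04 to 87.5. Undivided cells had lower means than polyclonal cells for Th17 (−0.55, 0.04, 8 of 9 members lower; 14.7 without Il17a), Treg (−0.32, 0.29, 13 of 14) and Tfh genes (−0.30, 0.67, 8 of 11; 22.0 without Angptl2), and higher ones for Th1 (0.19, 98.95, 10 of 13 members higher; 84.0 without Ccl5) and cytotoxic genes (0.21, 98.8, but only 4 of 8 higher; 81.7 without Klrd1). NK and innate lymphoid markers also had a higher mean (0.38, 99.4, 2 of 4 higher), and the other marker lists measured lay at percentiles 4.07 to 83.5. Il18rap belongs to both this list and the Th1 list. The interval from Wwox to 100 kb beyond Maf (chr8:114439635-115806894) held 75 regions, of which 28 were called in all 3 libraries, 20 in divided and polyclonal cells only, 16 in divided cells only and 1 in undivided cells only. At Cd8a, the region chr6:71376213-71377012 inside the gene was called in undivided (pileup 10) and polyclonal cells (16) and not in divided cells.

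The first pattern is the larger number of regions called in divided and not undivided cells. Weak calls near the authors' threshold on the calling side do not make up the excess, since the divided share was 75.2% at a −log10 q of at least 10. That cut acted on the calling side only, and a deeper library reaches a higher −log10 q at equal enrichment. The rise in share therefore says nothing about depth. Greater depth of the divided library cannot be told apart from a wider set of open regions: with pileups scaled by shared regions the share was 68.0% depth-limited (67.0 to 69.0) and 70.3% with a common minimum, but scaled by background it was 48.3% (47.2 to 49.4) and 56.5% (55.6 to 57.4). Which scaling is right is not fixed by the peak lists. In simulated unchanged libraries at about the background ratio, depth alone gave 72.2% at a fixed threshold and 47.8% with the common minimum. Depth-limiting there left 303 against 309 regions. The smaller pileup ratio of shared regions was not simulated, so these values do not show what depth alone would give here.

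The second pattern is the excess of divided-only regions at Tfh genes. Depth is argued against, since the list was at percentiles 99.86 and 99.825 when only regions that undivided cells could have called were counted, scaled by shared regions and by background. In the main setting the outcome recorded for a call resting on 1 gene was met, with a percentile of 95.2 without Icos. Depth-limited, a setting added later, the lowest with 1 member left out was 97.8 and 98.3 by the 2 scalings. A call resting on 1 gene therefore cannot be told apart from a wider excess. The call did depend on the assignment of regions to genes, with percentiles of 89.2 within 20 kb and 93.0 by gene span. Both lay inside the range of random lists, the outcome written beforehand for that explanation. The difference in division between the fractions stays open, as an untested explanation with 1 library each.

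The third pattern is the height of a few regions of the beta locus in both CBir1 libraries, 3 of the 17 called in all libraries, while 13 in divided and 10 in undivided cells were below 2 times the polyclonal value. The use of the same single-copy segments by every CBir1 cell is argued against as the whole cause, since the region behind the constant genes, which all T cells with a rearranged beta locus keep, was 4.18 and 7.61 times as high. Additional copies of the receptor transgene are a candidate explanation that was not tested. The polyclonal library is a mixture of receptors, so part of the ratio at the V segment may also reflect clonal use.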
